A study of Mus musculus with 16 samples.

How the data were processed

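Left ventricular RNA from 16 mouse samples in 4 groups of 4 was measured on Illumina BeadChips. Per the labels' protocols, total RNA was extracted with Trizol and RNeasy columns, checked on a Bioanalyzer and turned into biotin-labelled cRNA with an Ambion kit. GenomeStudio and lumi are named per the submitters' processing notes, with versions not given in the sources used here. The values used are log2 intensities as deposited by the authors for 25697 probes on 16 arrays. The sorted columns differed by at most 0.00123, so the authors' values were quantile normalised, with a median of 6.90 on every array and a range from 5.78 to 15.0. Whether the log2 scale of the deposited values came from a plain logarithm or a variance-stabilising transform, and whether background was subtracted, is not given in the sources used here. Either would change the fold changes of dim genes most. A further table with 64 columns of per-sample values was not used, because its column names match no label. The analysis fixed before the data were examined had assumed signals with detection p-values and a background correction with an offset of 16, so the deposited log2 values and the filter below took their place.

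Quantile normalisation fixes the number of probes above any level on an array, so such a number says nothing of array quality. Gene symbols came from the platform annotation: 23978 probes had 1 symbol, 0 had several and 1719 had none. Of the probes, 23962 matched the reference gene table by Entrez identifier, which changed 0 symbols. No genome build is given in the sources used here, so no coordinates are printed. Background was set as the 95th percentile of 1356 probes of chemosensory receptor genes, 7.13 on the log2 scale, with a median of 5.99 for those probes. Probes above it on at least 4 arrays were kept (13020), and the probe with the highest mean stood for each gene (9119 genes, 2277 of them with more than 1 such probe). Where all arrays of a group lay below background, the fold is a bound, written as at least N-fold, of the brighter group's mean against the dim group's mean of, per array, the higher of the background level and the probe's own value.

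The model was limma's linear fit of 4 group means over all 16 arrays with empirical Bayes moderation (12 residual and 3.15 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. All 16 arrays entered 1 fit, so the groups share an estimate of the spread. The 6 comparisons were each treated group with control, the combination with each single treatment, and the interaction of both treatments. For 30 gene lists, fixed before the data were examined and tested where at least 5 members passed the filter, camera was run with a preset correlation of 0.01, again with an estimated correlation, and fry was run as an alternative. Lists were adjusted over all lists of a comparison. The named genes were chosen by a rule fixed at the same time: the 10 highest and 10 lowest changes that passed with all 4 treated arrays on one side of the control arrays, 5 and 5 for the other comparisons, up to 4 members of each list with the smallest adjusted p, and 18 genes named whatever their value. Predicted gene models, unnamed genes, Y-linked genes and Xist were passed over.

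The labels give the groups the same replicate numbers, and whether these pair the samples was checked from the data. Deviations from the group means correlated positively in all 24 same-numbered pairs (r from 0.115 to 0.452, median 0.281). The fit with the replicate number as a block is given where it changes a call or moves a count. Pairs with different numbers within replicates 1 and 2 or within 3 and 4 correlated about as well (median 0.232), while pairs across these 2 sets had a median of -0.258. The correlations therefore show the 2 sets, and whether the numbers also pair the samples stays open. The slide and scan date of each array are not given in the sources used here. The alternatives were other filters, every probe tested by itself, a trended robust variance, array weights, the block, a fold threshold of 1.5, fits of only 8 arrays, each array left out in turn, and, chosen after seeing the data, cyclic loess, median centring, the 2 sets of arrays and a covariate for atrial genes.

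The fit was tested on simulated data for the combination against control with 9119 genes. Of 50 genes changed by each fold, it called 15 at a fold of 1.5, 31 at 2, 48 at 4 and 50 at 8. In all 155 genes were called, 11 of them unchanged, with 0 calls for AngII and for L-NAME, and 1 list shifted by 0.5 was called as the only list. The simulated noise was drawn independently for each gene, with no sets of arrays and no array standing apart. It therefore does not show how the list test fares where genes vary together. For comparisons with shared controls, 20 simulations of unchanged groups and 6 assignments of control arrays in separate pairs were used. The software was R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.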

Results

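Gene expression was measured in left ventricular tissue of male C57BL6 mice on 16 Illumina BeadChip arrays, 4 for each of 4 groups. The mice were 12 weeks old when they were assigned at random. The control group was compared with mice given L-NAME, an inhibitor of nitric oxide synthases, at 0.3 mg/ml in drinking water with 1% NaCl for 5 weeks. Another group received angiotensin II (AngII), a peptide that raises blood pressure, at 0.7 mg/kg/day from an implanted pump for 4 weeks. The combination group received both treatments and is the series' model of non-ischemic heart failure, set up to study mitochondrial function. The labels do not say whether the control or AngII mice drank salt, so the effects of L-NAME and of salt could not be separated. Values are log2 levels as deposited, with a median of 6.90 on every array, and 9119 genes had a probe above background. With 4 arrays per group the number of arrays limits the precision. The labels number the samples of a group from 1 to 4 but do not say that each came from a separate mouse, so p-values measure the spread between these samples.

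The comparison of the combination with the control group asks what changed in the failing left ventricle. Angptl7, a secreted angiopoietin-like protein, went from 8.29 ± 0.64 to 11.89 ± 0.99 (SD, n = 4), a 12.1-fold rise (limma adjusted p = 0.00211). Nox4, an NADPH oxidase that makes hydrogen peroxide, rose 7.50-fold from 7.11 ± 0.12 to 10.02 ± 0.24 (adjusted p = 0.000816), with 2 of the 4 control arrays above background. Dkk3, a secreted protein of the Dickkopf family, rose 6.90-fold (2.79 ± 0.32 log2 units, SE, adjusted p = 0.000282), and its second probe gave 2.47. Lox, which cross-links collagen and elastin, rose 4.52-fold from 8.80 ± 0.19 to 10.98 ± 0.21 (adjusted p = 0.000214).

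The other genes among the 10 highest rises were Mfap5, a microfibril protein (4.46-fold), Lcn2, the acute-phase protein lipocalin 2 (4.44-fold), Fam107a (4.05-fold), Comp, cartilage oligomeric matrix protein (3.86-fold), Pamr1 and Ankrd2. Pamr1 lay below background on all control arrays and rose at least 3.36-fold. Ankrd2, a muscle ankyrin repeat protein, lay below background in the other 3 groups and rose at least 2.18-fold (adjusted p = 4.24e-05). Lcn2 was above background on 3 control arrays and Comp on 2. The largest falls were in Ano10, a member of the anoctamin family, which fell by 2.35 ± 0.23 log2 units (SE, adjusted p = 9e-05), and Tbc1d10c, a GTPase-activating protein that inhibits calcineurin, which fell by 2.04 ± 0.20 (adjusted p = 7.81e-05). They were followed by Itgb6 (-1.95), the potassium channel subunit Kcnv2 (-1.62), the chemokine Cxcl9 (-1.55), Ddit4l (-1.51), Cd274 (-1.35), the vomeronasal receptor Vmn1r65 (-1.35), the phosphorylase kinase subunit Phkg1 (-1.35) and Pigz (-1.30). In the combination group Vmn1r65 was above background on 1 array, Ddit4l on 2, and Itgb6, Cxcl9 and Pigz on 3. The Vmn1r65 probe is itself among the chemosensory receptor probes that set the background, and whether it measures that gene here was not tested. The call of Itgb6 was lost without control array 4 (adjusted p = 0.0653), and that of Cxcl9 without control array 1, 3 or 4 (adjusted p = 0.0534, 0.0666 and 0.0638).

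In all, 528 genes changed between the combination and control groups (limma, Benjamini-Hochberg adjusted p under 0.05), 269 higher and 259 lower, with a median absolute change of 0.68 log2 units. The 4 arrays of one group lay entirely to one side of the other in 1152 genes (12.6%, against 2.86% by chance), among them 488 of the 528. Leaving out control array 1, 2, 3 or 4 gave 248, 309, 295 and 307 genes, and leaving out combination array 1 or 3 gave 285 and 304. Combination array 4 stood apart from its group, and without it 580 genes passed, of which 402 were among the 528.

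**Figure D1:**
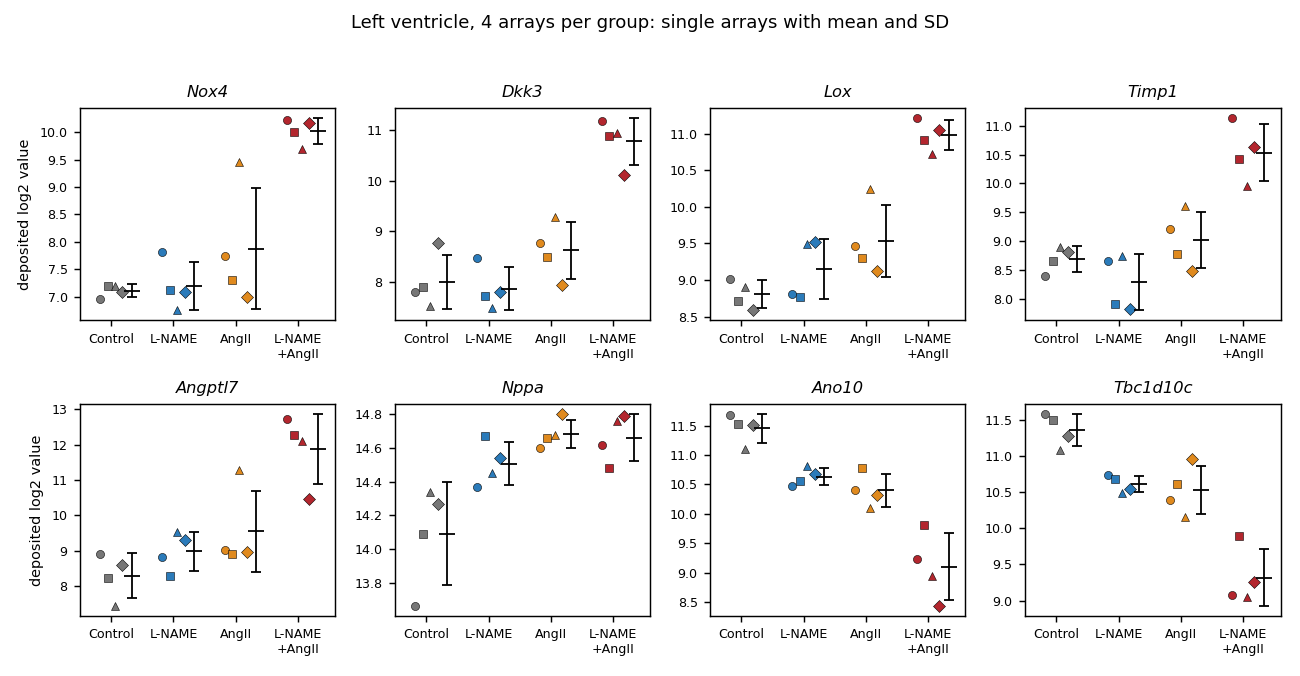
Deposited log2 values of 8 genes on each array (y axis) in the 4 groups (x axis), with marker shapes for the replicate number (circle 1, square 2, triangle 3, diamond 4) and bars for the group mean and SD. All 4 combination arrays lie above every other array for Nox4, Dkk3, Lox and Timp1 and below every other array for Ano10 and Tbc1d10c, whereas Nppa overlaps between the AngII and combination groups.

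Extracellular matrix and fibrosis genes rose as a group, with a median of 0.61 log2 units over 29 tested members (camera adjusted p = 2.41e-11; adjusted p = 0.16 with an estimated correlation). Of these, 9 rose and 20 did not pass, and 15 rose when adjusted over the list alone. Besides Lox and Comp they included Timp1, an inhibitor of matrix metalloproteinases, at 3.59-fold (8.69 ± 0.22 to 10.53 ± 0.50, SD, n = 4, adjusted p = 0.00213). Elastin (Eln) rose by 0.90 ± 0.11 log2 units (SE) and the proteoglycan biglycan (Bgn) by 0.88 ± 0.13. Fibrillar collagens did not pass: Col1a1, above background on 3 of the combination arrays, differed by 1.30 ± 0.52 (adjusted p = 0.163) and Col3a1 by 0.45 ± 0.36 (adjusted p = 0.515). Without combination array 4, 20 matrix genes rose, among them Col1a1 (2.04, adjusted p = 0.000358) and Col3a1 (0.94, adjusted p = 0.00919). Ccn2, or connective tissue growth factor, differed by 0.37 (adjusted p = 0.0671, and 0.0448 with the replicate block). Postn, which encodes periostin, was too dim to be tested, at 7.12 ± 0.12 in the combination and 6.15 ± 0.29 in the control group.

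Fibroblast markers had a median of 0.27 over 14 members (camera adjusted p = 0.0474; adjusted p = 0.495 with an estimated correlation). Mfap5 and Mfap4 rose, and 12 members did not pass; the count adjusted over the list alone was also 2. The call of Mfap4 (1.81) was lost without control array 1 or combination array 1 (adjusted p = 0.057 and 0.0533). The list's call was lost with the replicate block (adjusted p = 0.0554) and in 10 of the leave-one-out fits. Those without control array 1 or 3, L-NAME array 2, 3 or 4, or AngII array 1 or 2 gave adjusted p = 0.0606, 0.0704, 0.0539, 0.0503, 0.0509, 0.0519 and 0.0513. Without combination array 1, 2 or 3 the median was 0.18, 0.15 and 0.20 and the adjusted p 0.0822, 0.173 and 0.158, whereas without combination array 4 the median was 0.48 (adjusted p = 1.09e-05) and 6 members rose. With the mean of 3 atrial genes as a covariate the call was also lost (median 0.19, adjusted p = 0.207).

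The hypertrophy and fetal gene programme rose, with a median of 0.61 over 14 members (camera adjusted p = 7.82e-05; adjusted p = 0.16 with an estimated correlation). Of its members 4 rose and 10 did not pass, while 9 rose when adjusted over the list alone and 7 passed without combination array 4. Only Fhl1 passed without control array 1 or 2 or combination array 1 or 3 or with the mean of 3 atrial genes as a covariate, and 2 members passed without L-NAME array 1 or 4 or combination array 2. The muscle adaptor gene Xirp1 lost its call in all of these fits and without control array 3 or 4 (adjusted p from 0.0522 to 0.0992 with an array left out and 0.104 with the covariate). The calcineurin regulator Rcan1 lost its call with the covariate (adjusted p = 0.126) and in every leave-one-out fit except those without L-NAME array 3 or combination array 4 (adjusted p from 0.0523 to 0.128). Fhl1, a LIM-domain protein of the sarcomere, rose by 0.95 ± 0.11 log2 units (SE, adjusted p = 0.000282). Nppa, the precursor of atrial natriuretic peptide, rose by 0.57 ± 0.14 from 14.09 ± 0.31 (SD, n = 4, adjusted p = 0.0264). Its call was lost without control array 1 or 2 or combination array 1 or 3 (adjusted p = 0.0631, 0.0574, 0.0536 and 0.0648), and with the mean of 3 atrial genes as a covariate (0.52, adjusted p = 0.0661). Nppb, the precursor of brain natriuretic peptide, differed by 0.41 (adjusted p = 0.0612), skeletal alpha-actin (Acta1) by 0.44 (adjusted p = 0.0906) and the fetal myosin heavy chain Myh7 by 0.77 ± 0.47 (adjusted p = 0.368). Without combination array 4, Nppb passed (0.47) and so did Myh7 (1.33), both at adjusted p = 0.0352. The adult myosin heavy chain Myh6 differed by -0.17 (adjusted p = 0.384).

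Mitochondrial gene groups fell by small amounts. Complex I subunits had a median of -0.09 over 33 members, 29 of them negative (camera adjusted p = 0.00562; adjusted p = 0.16 with an estimated correlation). Ndufab1, the mitochondrial acyl carrier protein, fell by 0.86 ± 0.14 log2 units and Ndufb2 by 0.66 ± 0.14 (SE), and 31 members did not pass. The number that fell was 4 adjusted over the list alone, 5 with the replicate block and 6 without combination array 4. Mitochondrial ribosome genes had a median of -0.17 over 34 members (camera adjusted p = 0.00603; adjusted p = 0.25 with an estimated correlation), and 3 fell, as many as when adjusted over the list alone. Mrps15 fell by 0.86 ± 0.11 (adjusted p = 0.000556) and Mrps28 by 0.52 ± 0.09 (adjusted p = 0.00351). The ATP synthase epsilon subunit gene Atp5e fell by 0.68, the only one of 40 members of complexes II to V to pass, and that list missed the threshold (median -0.06, camera adjusted p = 0.0567) but passed without combination array 4 (same median, adjusted p = 0.0159).

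Genes of fatty acid uptake and oxidation fell as a group, with a median of -0.23 over 31 members (camera adjusted p = 0.000424; adjusted p = 0.32 with an estimated correlation). Of these 3 fell and 28 did not pass, while 8 fell when adjusted over the list alone and 6 fell and 1 rose with the replicate block. Only Hadh passed without control array 1, 2 or 3 or L-NAME array 1, and 5 members passed without combination array 2. In those first 4 fits the calls were lost for Eci1 (adjusted p = 0.108, 0.0636, 0.0697 and 0.0504) and Acot1 (adjusted p = 0.0997, 0.0699, 0.0953 and 0.0504). They were also lost with the mean of 3 atrial genes as a covariate (adjusted p = 0.06 and 0.0509). That of Eci1 was also lost without combination array 1 or 4 (adjusted p = 0.0648 and 0.0624), and that of Acot1 without L-NAME array 4 or AngII array 1 (adjusted p = 0.0506 and 0.0508). Hadh, which catalyses a step of beta-oxidation, fell by 1.01 ± 0.19 log2 units (SE, adjusted p = 0.00859). Cpt1b, which governs fatty acid entry into mitochondria, differed by -0.03 (adjusted p = 0.948), and Pdk4, the kinase that inhibits pyruvate dehydrogenase, by -0.72 (adjusted p = 0.4), or by -0.000643 without combination array 4 (adjusted p = 0.998). Without combination array 4 the list's median was -0.13 (adjusted p = 0.00172). The regulators of mitochondrial and fatty acid genes did not pass: Ppargc1a differed by -0.24 (adjusted p = 0.245), Ppara, above background on 2 control and 3 combination arrays, by 0.23 (adjusted p = 0.69) and Esrra by -0.33 (adjusted p = 0.0759, and 0.0457 with the replicate block). Among 21 genes of the TCA cycle and pyruvate dehydrogenase, Pdp2, a pyruvate dehydrogenase phosphatase, fell by 0.61 and the list missed the threshold (median -0.11, camera adjusted p = 0.067). Glycolysis genes had 3 rises among 23, including the phosphofructokinase Pfkp (1.07, adjusted p = 0.00555) and Ugp2 of glycogen synthesis (0.95, adjusted p = 0.00597), with a median of 0.10 (camera adjusted p = 0.0795), or 0.01 without combination array 4 (adjusted p = 0.123).

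Atrial and conduction markers had a median of 0.72 over 9 members, of which 8 were positive (camera adjusted p = 0.00316; adjusted p = 0.25 with an estimated correlation). Dkk3 belongs to this list and rose, as did the other two risers Myl1 and Clu, while Stard10 fell by 1.27 (adjusted p = 0.0076). The call of Myl1 (0.73) was lost without control array 1 (adjusted p = 0.0534), and that of Clu (0.46) without control array 3 or 4 or combination array 1 or 3 (adjusted p = 0.059, 0.0605, 0.0537 and 0.0581). Adjusted over the list alone, 4 rose and 1 fell. The mean of the atrial genes Myl4, Myl7 and Sln was 9.17, 8.12, 10.55 and 7.81 on the combination arrays and 9.78 on control array 4, against 6.94 to 7.73 on the other 11 arrays. With that mean as a covariate Dkk3 rose by 2.48. The list holds these 3 genes, so its other 6 were tested instead, a choice made after seeing the data. Their median was 0.53 (camera adjusted p = 0.00806), and with the covariate 0.52 (adjusted p = 0.035).

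Interferon response genes had a median of -0.30 over 17 members (camera adjusted p = 0.0474; adjusted p = 0.469 with an estimated correlation), and 1 fell, or 3 when adjusted over the list alone. Without L-NAME array 3 or AngII array 4, 2 members fell, and 3 without combination array 2. The single gene, the immunoproteasome subunit Psmb9, fell by 1.20 ± 0.21 log2 units (SE, adjusted p = 0.00433). The list's call was lost with the replicate block (adjusted p = 0.0554) and without control array 1, 3 or 4 (adjusted p = 0.0606, 0.0667 and 0.0905) or L-NAME array 2, 3 or 4 (adjusted p = 0.0539, 0.0503 and 0.0509). It was also lost without AngII array 1 or 2 (adjusted p = 0.0519 and 0.0513) or combination array 1 (adjusted p = 0.0732), and without combination array 4 the median was -0.05 (adjusted p = 0.257). Single members of other lists passed without a call for their list. Serpina3n, an acute-phase protease inhibitor, rose 3.38-fold and the chemokine Ccl11 fell by 0.73. Smooth muscle actin (Acta2) rose by 0.88, galectin 3 (Lgals3), a macrophage marker, by 1.12 and the early growth response gene Egr2 by 1.45.

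Genes of nitric oxide, cyclic GMP, angiotensin and endothelin signalling, the systems the treatments act on, gave no call among 20 members by limma and none adjusted over the list alone, with a median of 0.18 and 16 positive values (camera adjusted p = 0.0781). Endothelial nitric oxide synthase (Nos3) differed by 0.38 (adjusted p = 0.0954, and 0.0144 without combination array 4) and the angiotensin receptor Agtr1a by 0.20 (adjusted p = 0.328). The sarcoplasmic calcium pump gene Atp2a2 differed by 0.05 (adjusted p = 0.828).

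The remaining lists were not called for the combination against the control group. Immediate early genes had a median of 0.28 with 1 rise among 17 members (camera adjusted p = 0.0567), endothelial markers of 0.13 with 1 rise among 18 (camera adjusted p = 0.0567), circadian clock genes of 0.22 with none of 14 passing (camera adjusted p = 0.0781) and smooth muscle markers of 0.29 with 1 rise and 1 fall among 12 (camera adjusted p = 0.316). Mitochondrial biogenesis genes had a median of -0.15 with 1 fall among 22 (camera adjusted p = 0.0781), mitochondrial chaperones of -0.07 with 1 fall among 18 (camera adjusted p = 0.189) and calcium handling genes of -0.16 with 1 rise and 3 falls among 19 (camera adjusted p = 0.316). Antioxidant genes, to which Nox4 belongs, had a median of 0.00 (camera adjusted p = 0.618), the branched-chain, ketone and creatine list of -0.06 (camera adjusted p = 0.618), cytokines of -0.05 (camera adjusted p = 0.763) and macrophage markers of 0.06 (camera adjusted p = 0.732). Medians were -0.02 for endoplasmic reticulum stress and 0.03 for the cell cycle (both camera adjusted p = 0.98), -0.57 for lymphocyte, granulocyte and antigen presentation markers (camera adjusted p = 0.636), 0.12 for erythroid markers (camera adjusted p = 0.723), -0.07 for adipocytes (camera adjusted p = 0.525) and -0.07 for skeletal muscle (camera adjusted p = 0.618). Immediate early genes (0.30, adjusted p = 0.00172) and endothelial markers (0.20, adjusted p = 0.00702) passed without combination array 4. So did mitochondrial biogenesis genes (-0.16, adjusted p = 0.0254). Medians without that array were -0.34 for erythroid markers, -0.20 for lymphocyte, granulocyte and antigen presentation markers, 0.09 for clock genes and 0.17 for macrophage markers. They were -0.20 for skeletal muscle, 0.01 for adipocytes and -0.11 for the branched-chain list. None of these lists passed. Of the 4 calcium handling genes, 2 passed without control array 1 or combination array 1, and only Kcnv2 without control array 3. The rise among endothelial markers was lost without control array 2 or 3 or combination array 3 and with the mean of 3 atrial genes as a covariate, and the fall in biogenesis without control array 1. Among chaperones the fall of Hspe1 was lost without control array 1, 2 or 3 or combination array 1 or 3 (adjusted p from 0.061 to 0.0685) and with that covariate (adjusted p = 0.0642). Without combination array 3 and with the covariate Trap1 passed instead. The fall among smooth muscle markers was lost without control array 1, 2 or 3 or combination array 1, 2 or 4. In the fit that left out combination array 4, 4 immediate early genes and 3 endothelial markers rose, and 2 of each without combination array 2. Without control array 2, immediate early genes and endothelial markers also passed (both adjusted p = 0.0459). The epicardial list had 4 tested members and was not tested.

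**Figure D2:**
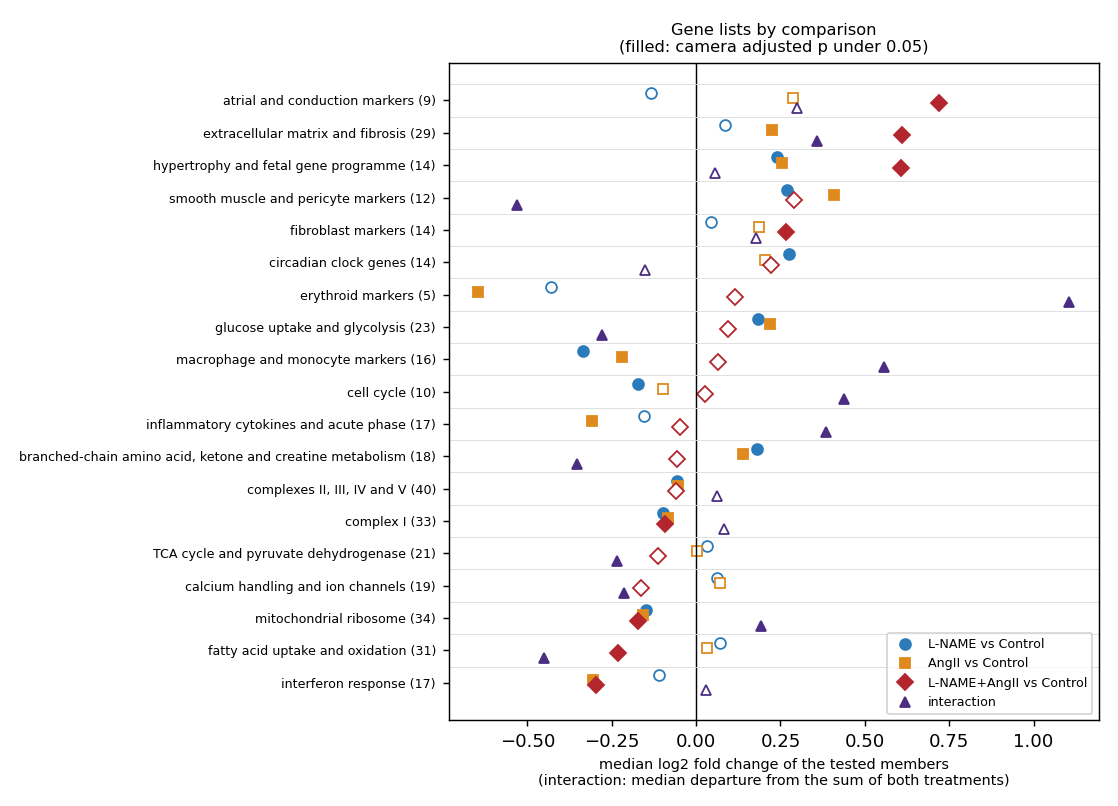
Median log2 fold change of the tested members (x axis) of each gene list called in at least 1 of the comparisons with control or in the interaction (y axis, number of tested members in parentheses), with filled symbols where camera gave an adjusted p under 0.05. The extracellular matrix list lies at 0.09 for L-NAME, 0.23 for AngII and 0.61 for the combination, and the fatty acid list at 0.07, 0.03 and -0.23.

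AngII alone was compared with the control group to see the effect of the single agent. Genes of glucose uptake and glycolysis rose as a group, with a median of 0.22 log2 units over 23 members, 18 of them positive (camera adjusted p = 0.00046; adjusted p = 0.0357 with an estimated correlation). This was the only list of the 6 comparisons whose call held with an estimated correlation, and with the replicate block added it did not (adjusted p = 0.052). Smooth muscle and pericyte markers rose (median 0.41, camera adjusted p = 0.00209; adjusted p = 0.138 with an estimated correlation), as did the hypertrophy programme (median 0.25, same camera adjusted p; adjusted p = 0.138 with an estimated correlation). The matrix list rose by a median of 0.23 (camera adjusted p = 0.00507; adjusted p = 0.437 with an estimated correlation) and genes of branched-chain amino acid, ketone and creatine metabolism by 0.14 (camera adjusted p = 0.0169; adjusted p = 0.366 with an estimated correlation). Mitochondrial ribosome genes fell (median -0.16, camera adjusted p = 0.000121; adjusted p = 0.086 with an estimated correlation), and so did complex I (median -0.08, 31 of 33 negative, camera adjusted p = 0.00199; adjusted p = 0.0913 with an estimated correlation) and complexes II to V (median -0.05, camera adjusted p = 0.00653; adjusted p = 0.138 with an estimated correlation). With an estimated correlation and the replicate block together, the mitochondrial ribosome and complex I lists both passed (adjusted p = 0.0344).

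Immune and blood cell lists also fell with AngII. Interferon response genes had a median of -0.31 (camera adjusted p = 0.00199; adjusted p = 0.336 with an estimated correlation) and inflammatory cytokines of -0.31 (camera adjusted p = 0.0169; adjusted p = 0.265 with an estimated correlation). Macrophage and monocyte markers had a median of -0.22 (camera adjusted p = 0.00209; adjusted p = 0.366 with an estimated correlation) and all 5 erythroid markers were negative, with a median of -0.65 (camera adjusted p = 0.0209; adjusted p = 0.437 with an estimated correlation). The branched-chain, cytokine and erythroid calls were each lost without control array 3 (adjusted p = 0.0611, 0.0975 and 0.0804). They were also lost without AngII array 4, 2 and 1, respectively (adjusted p = 0.117, 0.129 and 0.056), and the macrophage call without AngII array 4 (adjusted p = 0.0549). Of the medians, that of macrophage markers was -0.42 without AngII array 3 and -0.12 without AngII array 4, and that of the matrix list 0.15 without AngII array 3. The cytokine median was -0.20 without control array 3 and -0.19 without control array 4, that of the branched-chain list 0.09 without control array 4 or AngII array 4, that of the hypertrophy list 0.40 without control array 3, and that of complexes II to V -0.09 without AngII array 2. Leaving combination array 4 out of the shared fit added calls of the immediate early list (0.20, adjusted p = 0.0339), the circadian list (0.20, adjusted p = 0.0494) and fibroblast markers (0.19, adjusted p = 0.0326). It also added lymphocyte, granulocyte and antigen presentation markers (-0.44, adjusted p = 0.00963). With the mean of 3 atrial genes as a covariate, the immediate early list (0.30) and fibroblast markers (0.29) were called, both at adjusted p = 0.0256.

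No single gene passed for AngII by limma (smallest adjusted p = 0.0514), while 1314 genes (14.4%) had an unadjusted p under 0.05 and 1037 (11.4%, against 2.86% by chance) had no overlap between the groups. Xirp1 came closest, at 1.12 ± 0.21 log2 units (SE, adjusted p = 0.0514). Acta1 differed by 0.65 and Nppa by 0.59 (both adjusted p = 0.0932), Acta2 by 0.76 (adjusted p = 0.0652), Mrps28 by -0.45 (adjusted p = 0.0542) and Atp5e by -0.62 (adjusted p = 0.0932). Adjusted over the list alone, 6 glycolysis genes, 6 smooth muscle markers, 5 hypertrophy genes and 2 matrix genes rose, 5 mitochondrial ribosome genes fell, and 1 hypertrophy gene fell. With the replicate number as a block 56 genes passed, 27 higher and 29 lower, among them Xirp1, Fhl1 (0.49, adjusted p = 0.0436), Mrps28 and Atp5e. Other settings gave 7 genes with no filter, 125 with a stricter filter, 138 with a trended robust variance, 177 with array weights and 17 after median centring. Leaving out combination array 4 or 3 from the shared fit gave 137 and 10 genes, AngII array 4 gave 2, and AngII array 1 or L-NAME array 1 gave 1 each.

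L-NAME alone was compared with the control group in the same way. Macrophage and monocyte markers fell, with a median of -0.34 log2 units over 16 members, 13 of them negative (camera adjusted p = 0.000534; adjusted p = 0.316 with an estimated correlation). Mitochondrial ribosome genes fell by a median of -0.15 (camera adjusted p = 0.000255; adjusted p = 0.106 with an estimated correlation), complex I by -0.10 (camera adjusted p = 0.00542; adjusted p = 0.128 with an estimated correlation), complexes II to V by -0.06 (camera adjusted p = 0.0173; adjusted p = 0.199 with an estimated correlation) and cell cycle genes by -0.17 (camera adjusted p = 0.0312; adjusted p = 0.166 with an estimated correlation). Glycolysis genes rose (median 0.18, 19 of 23 positive, camera adjusted p = 0.00542; adjusted p = 0.106 with an estimated correlation), as did smooth muscle markers (median 0.27, camera adjusted p = 0.00582; adjusted p = 0.166 with an estimated correlation). Smaller calls were those of the hypertrophy programme (median 0.24, camera adjusted p = 0.0112; adjusted p = 0.207 with an estimated correlation), the branched-chain list (median 0.18, camera adjusted p = 0.0133; adjusted p = 0.334 with an estimated correlation) and circadian clock genes (median 0.28, camera adjusted p = 0.0312; adjusted p = 0.408 with an estimated correlation). With an estimated correlation and the replicate block together, the mitochondrial ribosome and complex I lists passed (both adjusted p = 0.045).

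No gene passed for L-NAME by limma (smallest adjusted p = 0.259), with 1043 genes (11.4%) at an unadjusted p under 0.05 and 918 (10.1%, against 2.86% by chance) without overlap between the groups. The other settings also gave 0 genes, except array weights, which gave 41. Acta1 differed by 0.59 ± 0.15 log2 units (SE), the endothelin precursor Edn1 by -0.63 ± 0.15, Ndufab1 by -0.59 ± 0.14 and Mrps15 by -0.51 ± 0.11, each at adjusted p = 0.259. The clock gene Per1 differed by 0.69 (adjusted p = 0.259) and Per2 by 0.75 (adjusted p = 0.274). Adjusted over the list alone, 4 hypertrophy genes, 2 smooth muscle markers and 1 clock gene rose, and 3 mitochondrial ribosome genes and 1 macrophage marker fell. The circadian call was lost without control array 1 (median 0.14, adjusted p = 0.147) and without L-NAME array 1 or 2 (adjusted p = 0.069 and 0.097), and its median was 0.15 without L-NAME array 4. The cell cycle call was lost without control array 2 (median -0.11, adjusted p = 0.109) and L-NAME array 2 or 3 (adjusted p = 0.103 and 0.0718), and its median was -0.28 without control array 1. Without control array 3 the glycolysis median was 0.08 and that of complex I -0.06; without control array 4 the branched-chain median was 0.10, and without L-NAME array 3 the hypertrophy median was 0.15. Leaving combination array 4 out of the shared fit added calls of matrix genes (0.09), cytokines (-0.15) and immediate early genes (0.17), all at adjusted p = 0.0471. It also added erythroid markers (-0.43, adjusted p = 0.0352). With the mean of 3 atrial genes as a covariate, matrix genes (0.21, adjusted p = 0.0372), immediate early genes (0.18, adjusted p = 0.024) and erythroid markers (-0.52, adjusted p = 0.03) were called.

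The combination was compared with AngII alone to see what L-NAME added. Matrix genes rose further, with a median of 0.44 log2 units over 29 members, 4 of which rose (camera adjusted p = 4.62e-08; adjusted p = 0.269 with an estimated correlation). Only Lox passed without AngII array 1, 2 or 4 or combination array 1, only Lox and Timp1 without combination array 2 or 3, and none with the mean of 3 atrial genes as a covariate. Dkk3 rose by 2.16 ± 0.32 (SE, n = 4, adjusted p = 0.0126), Ankrd2 at least 2.18-fold (adjusted p = 0.000353) and AA467197, above background on 2 AngII arrays, by 1.89 (adjusted p = 0.0126). Nox4 rose by 2.15 (adjusted p = 0.0219; 3 AngII arrays above background), Comp by 1.92 (adjusted p = 0.0321) and Timp1 by 1.52 (adjusted p = 0.0267). The largest falls were in Ano10 (-1.29, adjusted p = 0.0208), Tbc1d10c (-1.21, adjusted p = 0.0126), Phkg1 (-1.13, adjusted p = 0.0208), the carboxylesterase Ces1d (-1.09, adjusted p = 0.0208) and the D-lactate dehydrogenase Ldhd (-0.97, adjusted p = 0.0126). Of these genes only Ankrd2 and AA467197 kept their call with the mean of 3 atrial genes as a covariate. The change was then 1.65 for Dkk3, 2.23 for Nox4 and 1.64 for Timp1 (each adjusted p = 0.0838), 1.26 for Comp (adjusted p = 0.169) and -0.74 for Phkg1 (adjusted p = 0.117). It was -1.29 for Ano10 (adjusted p = 0.0857), -1.09 for Tbc1d10c (adjusted p = 0.0838), -1.26 for Ces1d (adjusted p = 0.0719) and -1.05 for Ldhd (adjusted p = 0.0623).

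Fatty acid genes fell against AngII, with a median of -0.38 over 31 members and 26 negative (camera adjusted p = 3.97e-07; adjusted p = 0.269 with an estimated correlation). None of them passed alone by limma; adjusted over the list alone 13 fell, and 9 matrix genes rose by that count. TCA cycle genes fell (median -0.14, camera adjusted p = 0.00963; adjusted p = 0.314 with an estimated correlation), as did the branched-chain list (median -0.20, camera adjusted p = 0.00581; adjusted p = 0.314 with an estimated correlation) and calcium handling genes (median -0.16, camera adjusted p = 0.02; adjusted p = 0.269 with an estimated correlation). Macrophage markers rose (median 0.25, camera adjusted p = 0.00115; adjusted p = 0.314 with an estimated correlation), as did cytokines (median 0.28, camera adjusted p = 0.00673; adjusted p = 0.269 with an estimated correlation). Erythroid markers rose by a median of 0.84 (camera adjusted p = 0.00938; adjusted p = 0.322 with an estimated correlation), a call lost without combination array 4 (median 0.19, adjusted p = 0.106). Atrial markers rose by a median of 0.26 (camera adjusted p = 0.00938; adjusted p = 0.314 with an estimated correlation). With the atrial mean as a covariate, the calls of the TCA cycle (-0.09, adjusted p = 0.326) and cytokines (0.35, 0.0564) were lost. The 6 atrial markers outside that mean had a median of 0.16 and did not pass (adjusted p = 0.244).

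Of all genes, 67 changed between the combination and AngII groups, 39 higher and 28 lower, and 704 (7.72%, against 2.86% by chance) had no overlap, among them 65 of the 67. The replicate block gave 172 genes, 89 higher and 83 lower, including all 67, with 7 matrix genes and 2 fatty acid genes among them; leaving out AngII array 1, 2 or 4 gave 22, 20 and 21 genes, combination array 1 gave 40 and combination array 4 gave 119. Without AngII array 1, 2 or 4 in turn, the calls were lost for Nox4 (adjusted p = 0.0619, 0.0773 and 0.0796), Timp1 (0.0563, 0.0843 and 0.0924), Comp (0.0835, 0.0939 and 0.11), Ano10 (0.0566, 0.0768 and 0.0558) and Ces1d (0.0619, 0.0707 and 0.0603). That of Phkg1 was lost without AngII array 1 or 2 (0.0619 and 0.0692). Without combination array 1 the calls of Nox4, Phkg1, Timp1 and Comp were lost (0.0508, 0.0508, 0.0702 and 0.0803), and that of Comp also without combination array 2 or 3 (0.0643 and 0.0658). Without combination array 2 the TCA and branched-chain calls were lost (both 0.0616), the matrix median was 0.28 and the atrial median 0.41, and without combination array 3 the atrial call was lost (0.0854). Without combination array 4 the medians of the matrix, cytokine and macrophage lists were 0.67, 0.43 and 0.39, and 12 matrix genes rose. Further lists called without it were fibroblast markers (0.21, adjusted p = 0.000104), hypertrophy (0.19, adjusted p = 0.00924), and lymphocyte, granulocyte and antigen presentation markers (0.29, adjusted p = 0.0133). Mitochondrial biogenesis (-0.13, adjusted p = 0.0361), endothelial markers (0.13, adjusted p = 0.0487) and immediate early genes (0.09, adjusted p = 0.0495) were likewise called. The cytokine median was 0.46 without AngII array 1 and 0.19 without AngII array 2, the calcium median -0.09 and -0.26 without AngII array 3 and 4, and the macrophage median 0.16 without AngII array 4.

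The combination was compared with L-NAME alone to see what AngII added. Matrix genes rose by a median of 0.58 log2 units, 5 of 29 passing and 13 adjusted over the list alone (camera adjusted p = 9.91e-11; adjusted p = 0.197 with an estimated correlation). Dkk3 rose by 2.92 ± 0.32 (SE, n = 4, adjusted p = 0.000393), Angptl7 by 2.90 ± 0.55 (adjusted p = 0.0126), Nox4 by 2.82 (adjusted p = 0.00146), Timp1 by 2.25 (adjusted p = 0.000867) and Mfap5 by 2.12 (adjusted p = 0.000566). The falls were led by the ribonuclease gene Rnase1, above background on 3 combination arrays (-1.91, adjusted p = 0.0454), Ano10 (-1.53, adjusted p = 0.00343), Phkg1 (-1.49, adjusted p = 0.00132), the acyl-CoA thioesterase Acot1 (-1.36, adjusted p = 0.0351) and Tbc1d10c (-1.29, adjusted p = 0.00326). Fatty acid genes fell by a median of -0.35, with 1 passing and 14 adjusted over the list alone (camera adjusted p = 1.47e-07; adjusted p = 0.197 with an estimated correlation). TCA cycle genes fell by -0.19, 1 passing and 6 adjusted over the list alone (camera adjusted p = 0.000594; adjusted p = 0.197 with an estimated correlation).

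The branched-chain list had a median of -0.17, with 2 falls and 1 rise (camera adjusted p = 0.00881; adjusted p = 0.296 with an estimated correlation). Macrophage markers rose by a median of 0.23 (camera adjusted p = 0.000594; adjusted p = 0.296 with an estimated correlation), atrial markers by 0.77 (same camera adjusted p; adjusted p = 0.197 with an estimated correlation) and the hypertrophy programme by 0.14 (camera adjusted p = 0.0224; adjusted p = 0.289 with an estimated correlation). In all 172 genes changed, 99 higher and 73 lower, and 941 (10.3%, against 2.86% by chance) had no overlap, among them 167 of the 172. The replicate block gave 262 genes, of which 164 were among the 172, and added a fall of the mitochondrial biogenesis list (adjusted p = 0.0403). Leaving out L-NAME array 1, 2, 3 or 4 gave 84, 97, 97 and 82 genes, and combination array 1 or 3 gave 104 and 110. The call of Acot1 was lost without any single L-NAME array (adjusted p = 0.0711, 0.0764, 0.101 and 0.0886), and that of Rnase1 in 13 leave-one-out fits (adjusted p from 0.0525 to 0.146). The hypertrophy call was lost without L-NAME array 4 (adjusted p = 0.0528) or combination array 1, 2 or 3 (adjusted p = 0.133, 0.0658 and 0.0623), with a median of 0.08 without combination array 1. The branched-chain call was lost without combination array 2 (adjusted p = 0.105). The fall in a TCA cycle gene was lost without L-NAME array 1, 2 or 4 or combination array 1, 2 or 3 or with the mean of 3 atrial genes as a covariate, and 2 fell without control array 4 or AngII array 3. No branched-chain gene passed without L-NAME array 1, 3 or 4 or combination array 1. A single one passed without control array 1 or 2, L-NAME array 2, AngII array 1 or 2 or combination array 2, or with that covariate. The branched-chain riser, Bdh1, passed in no leave-one-out fit but that without combination array 2. Without combination array 4, 16 matrix genes rose and 5 fatty acid genes fell, and the hypertrophy and macrophage medians were both 0.35. Fibroblast markers (0.42, adjusted p = 1.86e-06), mitochondrial biogenesis (-0.14, adjusted p = 0.00926), cytokines (0.07, adjusted p = 0.0299) and immediate early genes (0.06, adjusted p = 0.0414) were then called as well. With the atrial mean as a covariate 67 genes passed, 2 of them in the matrix list. The calls of Angptl7 (2.44, adjusted p = 0.105), Rnase1 (-1.73, 0.169) and Acot1 (-1.50, 0.087) were then lost. So was that of the hypertrophy list (0.07, adjusted p = 0.377). The 6 atrial markers outside that mean had a median of 0.29 (adjusted p = 0.0256), and with the covariate 0.26 (adjusted p = 0.181). Calls were added for calcium handling (-0.16, adjusted p = 0.0398), interferon response (-0.21, adjusted p = 0.0346) and erythroid markers (1.28, adjusted p = 0.0149).

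The interaction asks whether the combination departs from the sum of the 2 single treatments on the log2 scale. Macrophage and monocyte markers lay above the sum, with a median departure of 0.56 log2 units and 15 of 16 members positive (camera adjusted p = 8.06e-06; adjusted p = 0.161 with an estimated correlation). Fatty acid genes lay below it by -0.45 (camera adjusted p = 2.37e-05; adjusted p = 0.213 with an estimated correlation), and smooth muscle markers by -0.53, with all 12 members negative (camera adjusted p = 0.00201; adjusted p = 0.147 with an estimated correlation). Matrix genes lay above it by 0.36 (camera adjusted p = 0.00235; adjusted p = 0.355 with an estimated correlation). Cytokines lay above it by 0.38 (camera adjusted p = 0.00201; adjusted p = 0.147 with an estimated correlation), mitochondrial ribosome genes by 0.19 (camera adjusted p = 0.00416; adjusted p = 0.161 with an estimated correlation), cell cycle genes by 0.44 (camera adjusted p = 0.015; adjusted p = 0.147 with an estimated correlation) and erythroid markers by 1.10 (camera adjusted p = 0.00402; adjusted p = 0.277 with an estimated correlation).

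The other called lists lay below the sum of both treatments. The departure was -0.35 for the branched-chain list (camera adjusted p = 0.000546; adjusted p = 0.161 with an estimated correlation), -0.28 for glycolysis (camera adjusted p = 0.00492; adjusted p = 0.147 with an estimated correlation), -0.24 for the TCA cycle (same camera adjusted p; adjusted p = 0.222 with an estimated correlation) and -0.21 for calcium handling (camera adjusted p = 0.0317; adjusted p = 0.167 with an estimated correlation). Adjusted over the list alone, 7 TCA cycle genes, 6 branched-chain genes, 4 glycolysis genes, 3 calcium genes, 2 fatty acid genes and 2 smooth muscle markers lay below the sum, and 4 macrophage markers, 2 cytokine genes and 1 matrix gene above it. No single gene passed by limma (smallest adjusted p = 0.0548), with 1493 genes (16.4%) at an unadjusted p under 0.05; the replicate block gave 42, a stricter filter 148, a trended robust variance 156, array weights 179 and median centring 6. Timp1 departed from the sum by 1.92 ± 0.40 (SE, adjusted p = 0.065) and Acta1 by -0.80 ± 0.21 (adjusted p = 0.0982). Leaving out combination array 4, 3 or 2 gave 51, 15 and 1 genes, AngII array 3 gave 18 and control array 1 gave 7. The calcium call was lost without control array 1 or 2, L-NAME array 4 or AngII array 2 (adjusted p = 0.0676, 0.053, 0.0537 and 0.0536). Without combination array 4 the medians were 0.56 for matrix genes, 0.59 for cytokines, 0.10 for the mitochondrial ribosome and 0.58 for erythroid markers, and 5 more lists were called. These were lymphocyte, granulocyte and antigen presentation markers (0.73, adjusted p = 0.00441), interferon response (0.25), clock genes (-0.46), fibroblast markers (0.41) and atrial markers (0.40), the last 4 at adjusted p = 0.0132. With the atrial covariate, the calls of the matrix list (0.14, adjusted p = 0.208) and the TCA cycle (-0.16, 0.156) were lost.

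**Figure D3:**
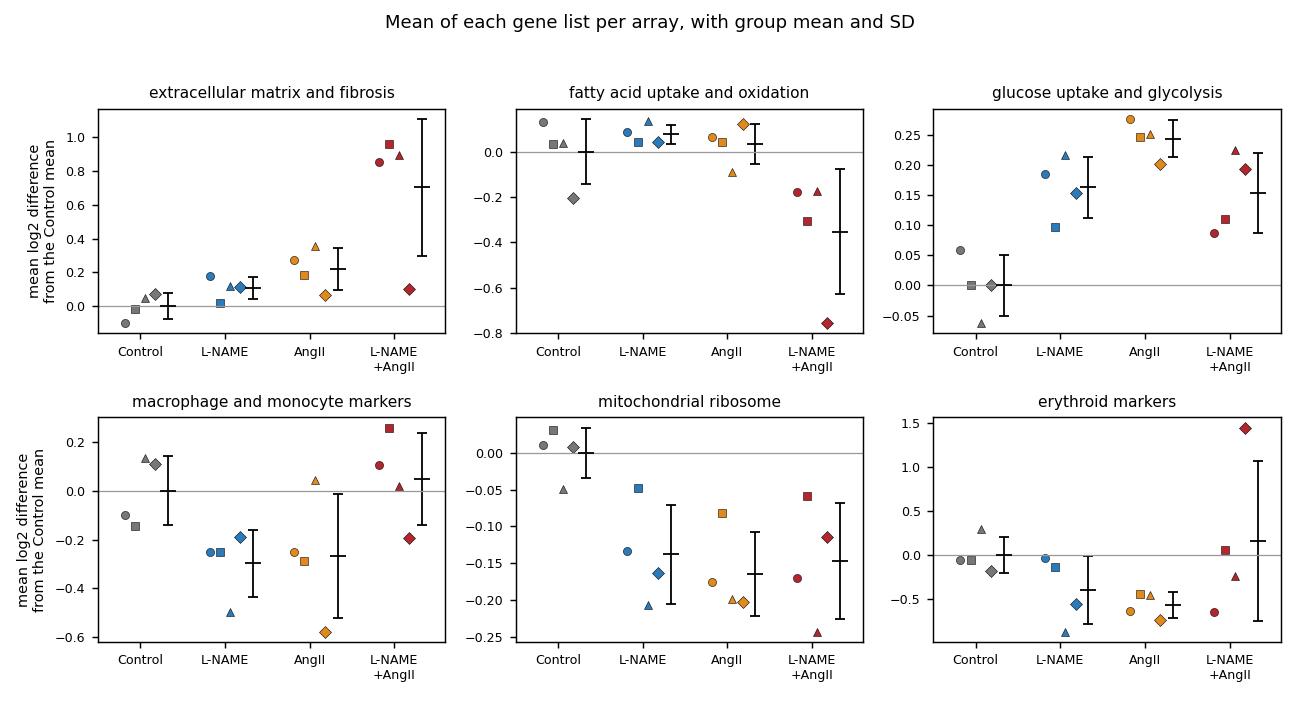
Mean log2 difference from the control group's mean (y axis) over the members of 6 gene lists on each array in the 4 groups (x axis), with marker shapes for the replicate number (circle 1, square 2, triangle 3, diamond 4) and bars for the group mean and SD. Combination array 4 lies below the other 3 of its group for the matrix and fatty acid lists and above them for erythroid markers, and the mitochondrial ribosome list lies lower on all 12 treated arrays than on 3 of the control arrays.

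The single treatments were set against each other and against the combination. Over 9119 genes, the log2 changes by AngII and L-NAME correlated at r = 0.743, against 0.507 for simulated groups with no effect that share the controls, and at 0.183 to 0.406 when each had its own 2 control arrays. The covariance was 0.049 against a simulated 0.0272, a difference of 0.0218. For the combination the correlation with AngII was 0.551 (covariance 0.0544, 0.0272 above the simulated value) and with L-NAME 0.473 (covariance 0.0407, 0.0135 above it). The second correlation lay below the simulated 0.507. With split controls the correlations were 0.12 to 0.428 with AngII and 0.0144 to 0.316 with L-NAME, and the covariances 0.0166 to 0.046 and 0.00185 to 0.0308. Genes are not independent replicates, so these correlations carry no p. Of the 528 genes changed by the combination, 492 (93.2%) had the same sign with AngII and 462 (87.5%) with L-NAME. Simulated groups gave 84.6%, but there the 528 genes were those with the largest change, not those that passed the test. That share is therefore not a like baseline, and whether the observed shares exceed chance cannot be told from it. The median ratio of the single to the combined change over these genes was 0.488 for AngII and 0.355 for L-NAME. With split controls 90 to 182 genes passed. Over those genes, not the 528, the shares were 78.6% to 94.4% for AngII and 65.5% to 84.4% for L-NAME. The median ratios were 0.291 to 0.413 and 0.144 to 0.229. With the replicate block, 20 of the 27 genes higher with AngII were also higher with the combination (1.14 for independent lists) and 23 of the 29 lower genes were also lower (1.28 for independent lists). Ranked instead by the change over the residual SD, without the block, the 27 highest genes of AngII shared 22 with the 386 highest of the combination. The simulated groups that share the controls gave a mean of 11 (highest 19), and split controls gave 10 to 19. For the 29 and 402 lowest genes the shared number was 28, against a simulated mean of 12.2 (highest 15) and 16 to 23 with split controls.

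A set of 49 genes changed in the combination against each of the other 3 groups, 31 higher and 18 lower. Leaving out AngII array 1, 2 or 4 gave 18, 19 and 21 genes, combination array 1 gave 28 and combination array 4 gave 92. The replicate block gave 96, and the atrial covariate gave 3. Lox (1.64, adjusted p = 0.0623) and Nupr1 (1.63, adjusted p = 0.0838) then missed the threshold against AngII. The 49 genes included Lox, higher by 2.18, 1.45 and 1.83 log2 units than in the control, AngII and L-NAME groups. As examples chosen after their values were seen, the sphingosine kinase Sphk1 was higher by 1.65, 1.71 and 1.79 and the stress-response gene Nupr1 by 1.47, 1.53 and 1.63. These comparisons share the combination arrays. Of the genes higher than in the control group, 32 were also higher than with AngII (1.15 for independent lists) and 82 higher than with L-NAME (2.92), and of the lower genes 19 and 48 were shared (0.795 and 2.07). Ranked instead by the change over the residual SD, the 39 highest genes against AngII shared 34 with the 269 highest against control. Simulated groups that share the combination arrays gave a mean of 11.9 (highest 19), and splitting those arrays gave 18 to 32. For the 28 and 259 lowest genes the shared number was 20, against a simulated mean of 8.1 (highest 15) and 11 to 23 with split arrays. The 99 highest genes against L-NAME shared 74 with the 269, against 25.2 (highest 32) and 44 to 59. The 73 lowest shared 47 with the 259, against 20.4 (highest 26) and 29 to 45.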

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

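Of the tests in this part, the probe count used to look for a noisy array and the interaction splits within replicate numbers were written before their results were seen; the other counts of splits and the other tests were chosen only after the results were seen. The 2 sets of arrays were defined from the data, not by the labels.

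Combination array 4 stood apart from its group, with a median correlation to its group of 0.941 against at least 0.968 for the other arrays and an array weight of 0.182 against 0.565 to 2.58. Extracellular matrix genes were lower on it than on the other 3 arrays by a median difference of -0.829 and fibroblast markers by -0.995. Erythroid markers were higher by 1.87 and clock genes by 0.93. Lymphocyte, granulocyte and antigen presentation markers had a median difference of -1.51, with 5 of 8 below all of the other 3 arrays of the group and 3 above them, among these S100a8 at 12.28. A label from another group is argued against, because the array lay at least 0.591 of the way from each other group to the rest of its own; a sample from outside the series stays open. Blood is argued against for the lower fatty acid genes (median -0.369), since 73 respiratory chain genes did not fall with them (median 0.0934, SD 0.264). A noisy hybridisation may contribute, as 146 chemosensory receptor probes were above background against 31 to 98 on the other 15 arrays, and no biological explanation was tested.

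Replicates 1 and 2 of all groups differed from replicates 3 and 4, with 1474 genes (16.2%) past the threshold between these sets of 8 arrays, 784 higher and 690 lower in replicates 3 and 4. Of the chemosensory receptor probes, 26.1% differed between the sets at an unadjusted p under 0.05, against 5.9% between the combination and control groups, and 79.1% of these were higher in replicates 3 and 4. A batch of arrays is a candidate explanation and stays open, as the slides are not given in the sources used here. With the set as a block, 834 genes changed with the combination, including all 528. Within replicates 1 and 2 the count was 276 and within replicates 3 and 4 it was 0, each with 2 arrays per group.

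The atrial genes Myl4, Myl7 and Sln differed by 1.02, 0.72 and 1.19 log2 units between the combination and control groups without passing. Over the 16 arrays they varied together (lowest pairwise r = 0.868), and control array 4 (9.78) lay among the highest means. Atrial tissue in some of the ventricle samples may account for these 3 genes. It is argued against as the whole cause for Dkk3 against control, which stood at 2.48 with their mean as a covariate and 2.79 without it. That mean is a rough measure, as Myl7 was above background on 1 control and 3 combination arrays and Sln on 2 and 3. Against AngII the change of Dkk3 went from 2.16 to 1.65 and lost its call (limma adjusted p = 0.0838), so atrial tissue stays open there. A change of Myl4, Myl7 and Sln within the ventricle stays open.

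The arrays of each comparison were split in all 35 ways into 2 groups of 4, the real split included. If the replicate numbers pair the samples, which stays open, the real split compares with the 8 splits, itself included, that part all 4 pairs. These are too few for a share under 0.05. For the combination against control the real count of 528 genes stood beside a highest other of 1, and that of 8 lists beside 15. Against AngII 67 genes stood beside 1 and 9 lists beside 7, and against L-NAME 172 genes beside 0 and 7 lists beside 14. For AngII the genes at an unadjusted p under 0.05 were 1314 beside 378 and the lists 12 beside 10, and for L-NAME 1043 beside 465 and 10 beside 7.

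The other splits keep at least 1 same-numbered pair together, so counts over all 35 leave any pairing out. Only with the pairing left out could chance be excluded for the 528 genes of the combination against control (1 of 35 splits; highest other 6), for the 172 genes against L-NAME (1 of 35; highest other 143) and for the genes at an unadjusted p under 0.05 with AngII (1314; 1 of 35; highest other 1198) and L-NAME (1043; 1 of 35; highest other 940). The highest other value was the split by sets in each of these 4 cases. The 12 lists of AngII (1 of 35; highest other 10) and the 10 lists of L-NAME (1 of 35; highest other 7) were likewise reached by no other split. For the 67 genes against AngII the share was not under 0.05 (2 of 35), because the split by sets gave 342, several times as many. That points to a structure of the samples. The set block gave 178 genes and kept all 67. Nor was the share under 0.05 for the 8 lists of the combination against control (5 of 35, highest other 15). The same held for the 9 lists against AngII (4 of 35, highest other 14) and the 7 against L-NAME (7 of 35, highest other 14). For the genes passing with AngII or L-NAME alone, where the real count was 0, all 35 splits gave as many and the highest other was 1.

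For the interaction 100 splits were drawn with the groups reassigned only within replicate numbers, as in the real split. As many as the 1493 genes at an unadjusted p under 0.05 came from the real split only (1 of 100, highest other 901). As many as the 12 lists came from 2 of 100 (highest other 12). Such splits also break up the effects of the single treatments, so they test for any difference among the groups. They cannot exclude chance for the interaction alone. In 100 splits that do not keep the replicate numbers apart, as many genes came from the real split only (1 of 100; highest other 1036). As many lists came from it and another (2 of 100; highest other 12), and the count of 0 genes from all (100 of 100; highest other 1).

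A sample far from the other 3 of its group was seen in 31 of 396 sets of a gene and a group, 12 of them on combination array 4, and in 7 of 116 sets of a list and a group, 2 of them on that array. Chance gives about 1 in 20. Aqp7, Ucp3, Angptl4, Cd74, H2-Eb1, Ciart, Chac1, Slc4a1, Alas2, S100a8 and Ddit3 were looked at because they stand apart on combination array 4, so their flags are not independent of it. On that array the log2 values were 6.45 for Aqp7, 5.86 for Ucp3, 8.77 for Angptl4, 7.95 for Cd74, 11.19 for Acot1, 13.99 for Bgn, 11.90 for Ces1d, 7.66 for Kcnv2 and 11.85 for Pdk4, each the lowest of its group, and 12.94 for Chac1, 9.67 for Hadh and 11.31 for Per2, each the highest. Slc25a42 was highest at 9.10 on combination array 1.

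On control array 4 the values were 11.14 for Agtr1a, 12.93 for Fhl1 and 8.58 for Fkbp5, each the lowest, and 10.87 for Chac1 and 11.88 for Myl4, each the highest, and Nupr1 was lowest at 8.88 on control array 3. On L-NAME array 3 Col3a1 was highest at 10.19 and Hadh lowest at 9.53. On AngII array 3 Angptl7 was highest at 11.28 and Hadh lowest at 9.09, and on AngII array 1 Mrps15 was highest at 10.96. On AngII array 4 the values were 14.70 for Ccn2, 8.81 for Edn1 and 7.37 for Slc4a1, each the lowest, and 12.65 for Ndufb2, 14.89 for Pdk4, 11.38 for Per1 and 10.16 for Slc25a42, each the highest. List means against the control mean that lay far from their group were 0.10 for the matrix list and -0.31 for fibroblast markers on combination array 4, -0.13 for the TCA cycle and 0.77 for atrial markers on control array 4, 0.18 for the hypertrophy list on AngII array 2, 0.28 for antioxidant genes on AngII array 3 and -0.20 for endoplasmic reticulum stress on AngII array 4.

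The effect of AngII differed with and without L-NAME, by the camera test of the interaction, in 12 lists. The median difference was 0.36 for the matrix list, 0.38 for cytokines, 0.19 for the mitochondrial ribosome, 0.44 for the cell cycle, 0.56 for macrophage markers and 1.10 for erythroid markers. It was -0.45 for fatty acid genes, -0.24 for the TCA cycle, -0.28 for glycolysis, -0.35 for the branched-chain list, -0.21 for calcium handling and -0.53 for smooth muscle markers. None of these calls held with an estimated correlation (smallest adjusted p = 0.147).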

How the results depend on the processing

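The stricter filter, cyclic loess, median centring, the set block, the fits of 1 set, the atrial covariate and the atrial list without the covariate's genes were chosen after seeing the data, as was leaving out arrays of groups outside a comparison and all list tests with an array left out. Counts of genes are given in the order combination against control, AngII, L-NAME, combination against AngII, combination against L-NAME and interaction, where the deposited values gave 528, 0, 0, 67, 172 and 0. Array weights gave 1106, 177, 41, 293, 478 and 179, the replicate block 788, 56, 0, 172, 262 and 42, the set block 834, 49, 0, 178, 293 and 80, and a trended robust variance 717, 138, 0, 168, 280 and 156. The stricter filter gave 672, 125, 0, 158, 235 and 148, no filter 411, 7, 0, 46, 118 and 0, and median centring 523, 17, 0, 79, 182 and 6. The atrial covariate gave 438, 13, 0, 3, 67 and 0, and a fold of at least 1.5 gave 334 for the combination against control. Replicates 1 and 2 alone gave 276, 0, 0, 40, 72 and 0 and replicates 3 and 4 alone gave 0 throughout, with fewer arrays. Fits of only 8 arrays gave 82, 0, 0, 3 and 51, also with fewer arrays. The replicate block kept 518 of the 528 genes, 67 of the 67 and 164 of the 172. Leaving out 1 array gave 248 to 580, 0 to 137, 0, 20 to 119, 82 to 216 and 0 to 51 genes. A further threshold accounts for the 334, and the cause of the other differences, fewer arrays among the candidates, was not tested. Replicates 1 and 2 and replicates 3 and 4 hold equal numbers of arrays. Fewer arrays alone therefore do not account for 276 genes against 0.

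Lists called numbered 8, 12, 10, 9, 7 and 12 in the same order. With an estimated correlation they were 0, 1, 0, 0, 0 and 0. Fry, which does not compare a list with other genes, gave 10, 6, 3, 6, 8 and 10. For the combination against control no filter gave 16, array weights 14, replicates 1 and 2 alone 14 and replicates 3 and 4 alone 2. For the combination against L-NAME no filter gave 11, replicates 1 and 2 alone 11 and replicates 3 and 4 alone 4, which also gave 3 against AngII and 6 for the interaction. The replicate block gave 6, 12, 10, 9, 8 and 12. Leaving out 1 array gave 6 to 11, 9 to 16, 8 to 14, 7 to 14, 5 to 11 and 11 to 17. The circadian median for the combination against L-NAME was -0.27 with replicates 1 and 2 alone and -0.02 with all arrays. The cause was not tested.

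Of 13749 values of named genes under the alternatives, 13133 kept their side of the threshold, 374 lost and 242 gained a call, and 0 calls turned. Among the 13133, 170 values that did not pass changed sign. Of 84 calls of named genes (67 genes), 48 were kept in all settings with 15 or 16 arrays. Among named genes the replicate block added 10 calls and ended 1 (Kcnj2) for the combination against control and added 5 for AngII; beside these and the 3 lists given in the results, it changed no other call of a named gene by limma or of a list by camera with the preset correlation. With an estimated correlation it ended the glycolysis call of AngII (adjusted p = 0.052) and added complex I and the mitochondrial ribosome for AngII (both 0.0344) and L-NAME (both 0.045). Detection of dim genes is limited by signal over background. Not run were a background correction with an offset of 16 or 50, no background correction, cyclic loess or median scaling after such a correction, a filter on detection p and the slide as a block, because the signals were not used and the slide is not given in the sources used here; the authors' deposited values, planned as an alternative, became the values used.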

Other observations

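Genes in this part were chosen after their values were seen, and the test of the gene list was chosen only after the result was seen. Some genes differed between the combination and each of the other 3 groups. Matrix Gla protein (Mgp), an inhibitor of calcification, was higher by 1.03, 0.85 and 1.21 log2 units than in the control, AngII and L-NAME groups, the membrane protein gene Emp1 by 1.01, 1.09 and 1.12, and the transforming growth factor beta receptor Tgfbr1 by 0.95, 0.53 and 0.79. The sodium channel subunit Scn4b was lower, with differences of -0.90, -0.74 and -0.78, as was the mitochondrial carrier Slc25a42, with -0.57, -0.86 and -0.85. None of these 5 genes passed against AngII with the atrial covariate (adjusted p = 0.0719, 0.0838, 0.152, 0.0583 and 0.0838 in that order). Slc25a42 then missed the threshold against control (adjusted p = 0.0535). The call of Tgfbr1 against AngII was lost without AngII array 1, 2 or 4 or combination array 1, 2 or 3 (adjusted p from 0.0595 to 0.104). That of Scn4b was lost without any single AngII array, L-NAME array 1 or 4, or combination array 1 or 2 (adjusted p from 0.0527 to 0.116). Against control, that of Slc25a42 was lost without control array 1 or 2 or combination array 3 (adjusted p = 0.0769, 0.0706 and 0.06).

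A set of 10 genes known to respond to glucocorticoids had been noticed among the genes that rose with the combination, including Fkbp5 (1.60 ± 0.32 log2 units, SE, adjusted p = 0.00983), Map3k6 (1.56 ± 0.22, adjusted p = 0.000991), Ddit4 (1.28 ± 0.16, adjusted p = 0.000471) and Tsc22d3 (0.96 ± 0.16, adjusted p = 0.00386). The others were Errfi1, Cdkn1a, Lcn2, Irs2, Fam107a and Nfkbia. A glucocorticoid response is a hypothesis that was tested on other textbook targets, a list completed after most members' values had been seen, so it is not independent evidence. These 25 genes had a median of 0.35, with 20 positive and 2 that rose, Sult1a1 and Anxa1 (camera p = 0.00206; p = 0.0497 with an estimated correlation). Their median was 0.295 with AngII and 0.13 with L-NAME, with 21 and 20 positive and 0 passing by limma in either. The combination stood at a median of -0.034 against AngII, with 10 positive, and at 0.0621 against L-NAME, with 14 positive and 1 passing. The departure from the sum of the 2 treatments was -0.243, with 7 positive. The list therefore does not set the combination apart from AngII alone. Hormone levels were not measured here, and these genes also respond to other stimuli, so the hypothesis stays open.

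The 3 probes of Nnt, a mitochondrial transhydrogenase, lay below background on all 16 arrays.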
